A study of Mus musculus with 6 samples.

How the data were processed

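The series holds 6 libraries of liver polyA RNA from wild-type C57BL6J mice, 3 from each of 2 diets, MCS and MCD, and samples were grouped by the diet given in their titles. Per the labels' protocols, RNA was extracted with Trizol, captured on mRNA beads, fragmented and made into cDNA libraries with adapters; the labels do not say whether the strand was kept. Per the submitters' processing notes, the genome build was GRCm39 and the tools were fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.1.0, StringTie 1.3.1 and RSEM, with no role or order given.

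The deposited table gives, per the file headers, a count and a TPM value for each gene and library, with the authors' mean TPM per group, log2 fold change, p-value and FDR, and gene annotation. The deposited counts are whole numbers, but 64 cells hold a count of 0 with a TPM above 0, so they were treated as estimated counts (RSEM-type expected counts) that had been rounded before deposit. The TPM columns deposited by the authors are scaled to the same total in each library. The log2 fold change deposited by the authors equals the log2 ratio of their mean TPM values in all 21899 rows within 1e-06, with a mean TPM of 0 replaced by 0.001, and the test behind the deposited p-value and FDR is not given in the sources used here. Fold changes in the deposited table therefore rest on TPM, in which a few abundant genes can move the values of all others, while the fold changes reported here rest on counts scaled by TMM. Genes with near-identical copies, such as the Mup, Cyp2 and glutathione transferase families, can exchange reads in such estimates, and their sums were tested beside the single genes.

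Counts were read with R 4.3.3 and tested with edgeR 4.0.16. Of 21899 genes, 5317 had a count of 0 in every library, and 12599 passed filterByExpr by group with a minimum count of 10; the lowest share of a library held by the tested genes was 99.9%. TMM factors were 0.816, 0.797 and 0.873 for MCS replicates 1 to 3 and 1.21, 1.04 and 1.41 for MCD replicates 1 to 3. The 50 most abundant genes of each library, which need not be the same genes, took 40.9%, 41.1% and 38.7% of the counts in the MCS and 33.7%, 36.5% and 30.2% in the MCD libraries. The quasi-likelihood fit with robust dispersions held diet as its only term, and genes were called at a Benjamini-Hochberg adjusted p under 0.05; SE values are the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. Total counts of 16615469 to 21322771 per library set the floor of 3 counts at 0.104 to 0.227 CPM, and floors and counting intervals (95%) cover counting error only. No replicate pair agreed within sampling noise: chi-square per degree of freedom was 17.4 between MCS replicates 1 and 2 and up to 199 between others.

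The comparison, the tests, 35 gene lists and the rule for named genes were fixed before the data were examined. The rule names the 6 genes that rose and the 6 that fell with the largest log2 fold change among called genes with a mean of at least 5 CPM, no overlap between the diets and a symbol that is not a predicted-gene name. For each biology or cell type list it names the 2 called members with the smallest p in the main direction and the 1 with the smallest p in the other, or, with none called, the member with the highest mean CPM. For each list kept as a check it names 1 member. Not every gene that the rule names is reported here. Other members of a list are named to show what did not pass or what else passed, and were chosen after their values were seen, as were the sums over families; each of these was also refitted with 1 library left out in turn, and the genes under the other scalings, filters and tests. The members Timd4, Cd8a, Gnmt, Mat2a, Cyp2b9 and Cyp3a11 passed the test and were refitted in this way, but are not described, a choice made after their refits were seen. Their calls ended in 4 or 5 of the 6 fits with a library left out, but so did the calls of some genes that are described. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 35 lists, each with at least 5 tested members. Pathways in the deposited annotation with 10 to 300 tested genes were tested one-sided in each direction, and human disease terms, 24 of the tests that passed, are not named.

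The scripts were tested on simulated data: counts drawn for 12599 genes with the real library sizes, means and dispersions, with 50 genes changed at each of 4 sizes. For the MCD against MCS comparison the test recovered 2 of 50 genes changed 1.5-fold, 19 of 50 changed 2-fold, 42 of 50 changed 4-fold and 44 of 50 changed 8-fold, with 4 false calls. A list shifted 2-fold was called, as was 1 of the other lists, and a pathway with 12 genes raised was called. Far fewer genes changed in the simulation than were called in the real data, which makes the adjusted threshold stricter. The recoveries therefore need not hold for the real comparison. Genes were drawn independently, so the list and pathway checks do not cover correlation between genes.

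Alternatives were other scalings (DESeq2 size factors, upper-quartile factors, library size alone, library sizes without the 50 most abundant genes), no filter (a total of at least 1 count) or a stricter one (at least 50 counts in 3 libraries), DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 0.5, a replicate block, leaving out each library, an adjusted p under 0.01, non-robust dispersions, removal of a gene length trend, and other list and pathway settings. Chosen after seeing the data were the fit without MCS replicates 1 and 2, the female-biased list without Prom1, list medians without both replicates 3, removal of a GC content trend, and library sizes without the 50 most abundant and the Mup genes with no scaling factor. GC content came from GENCODE M21 transcripts, matched by gene identifier for 99.9% of tested genes. No genome coordinates are given, because the annotation used here is of another build than GRCm39.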

Results

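Liver polyA RNA was sequenced from wild-type C57BL6J mice that had been fed for 6 weeks either a methionine- and choline-sufficient diet (MCS, 3 libraries) or a diet deficient in both nutrients (MCD, 3 libraries). The MCD diet is used in mice to model metabolic dysfunction-associated steatohepatitis (MASH), and the comparison asks how the liver transcriptome differs between the diets. Total counts were 21322771, 16615469 and 20783004 for MCS replicates 1 to 3, and 18443357, 21285045 and 20440745 for MCD replicates 1 to 3. At these depths 3 counts in a library correspond to 0.104 to 0.227 CPM (counts relative to the TMM-scaled library size). The first principal component of log CPM held 70.7% of the variance and separated the diets, with MCS libraries between −61.9 and −47.0 and MCD libraries between 28.3 and 85.1. The second component (12.3%) set replicate 3 of both diets (−39.1 for MCS, −25.5 for MCD) apart from the other libraries (9.73 to 32.5). The labels do not say that the replicates of a diet were separate animals, so p-values measure only the spread between these samples, which may be technical. Changes of single genes are log2 fold changes of MCD over MCS ± SE from edgeR's quasi-likelihood test with TMM scaling (n = 3 libraries per diet), with Benjamini-Hochberg adjusted p over 12599 tested genes. Levels are mean CPM ± SD over 3 libraries.

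On the MCD diet, 17 of 18 tested markers of recruited macrophages, 22 of 30 extracellular matrix genes and 20 of 23 cell cycle genes rose, and 13 of 15 male-biased liver genes and 15 of 26 fatty acid oxidation genes fell. These 5 lists passed camera, with adjusted p at most 3.16e-06 (adjusted p = 0.372 to 0.555 with an estimated correlation). With library size alone 13 of the male-biased and 8 of the fatty acid oxidation genes fell. Without MCS replicate 1, MCS replicate 2 or MCD replicate 1, 9, 4 or 10 of the extracellular matrix genes rose and 8, 7 or 6 of the fatty acid oxidation genes fell. The largest rises among genes with a mean of at least 5 CPM were those of Mmp12 (ENSMUSG00000049723), a macrophage elastase, from 2.40 ± 1.07 to 331 ± 169 CPM (7.13 ± 0.53, adjusted p = 0.000371), and of Adam8 (ENSMUSG00000025473), a membrane metalloprotease of myeloid cells, from 0.309 ± 0.0912 to 43.3 ± 17.9 CPM (7.11 ± 0.42, adjusted p = 8.67e-05). Gpnmb (ENSMUSG00000029816), a lysosomal glycoprotein of lipid-laden macrophages, rose from 4.46 ± 1.64 to 587 ± 299 CPM (7.05 ± 0.49, adjusted p = 0.000184). The glutathione transferase Gsta1 (ENSMUSG00000074183), the cytochrome P450 Cyp2a4 (ENSMUSG00000074254) and the estrogen sulfotransferase Sult1e1 (ENSMUSG00000029272) rose by 6.78 ± 0.36, 6.58 ± 0.56 and 6.09 ± 0.88 (adjusted p = 5.59e-05, 0.000485 and 0.00403). The steroid dehydrogenase Hsd3b5 (ENSMUSG00000038092) fell from 179 ± 36.5 to 0.280 ± 0.0758 CPM (−9.31 ± 0.29, adjusted p = 2.27e-06). The sum of 8 related Hsd3b genes, Hsd3b5 included, fell less, by 1.68 (adjusted p = 0.00314). Sult1e1 did not pass by limma-voom (log2 fold change 5.47, adjusted p = 0.128). Cyp2a4 had a log2 fold change of 5.97 without MCD replicate 3.

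Major urinary protein genes, which encode pheromone carriers secreted by the liver, made up most of the other large falls. Mup7 (ENSMUSG00000073842), Mup19 (ENSMUSG00000078673), Mup15 (ENSMUSG00000096674) and Mup17 (ENSMUSG00000096688) had log2 fold changes of −7.32 ± 0.55, −7.20 ± 0.54, −8.36 ± 0.66 and −8.18 ± 0.64 (adjusted p = 0.000193, 0.000193, 0.000265 and 0.000265). Of 19 tested Mup genes, 17 fell and 0 rose. These genes are near-identical copies whose reads the counting could divide, so single Mup values are uncertain. The summed family fell from 94089 ± 25828 to 11098 ± 2649.9 CPM (−3.08 ± 0.39, adjusted p = 0.00153). Mup transcripts took 8.05%, 9.33% and 5.77% of the counts in MCS replicates 1 to 3 and 1.39%, 1.40% and 1.16% in MCD replicates 1 to 3. Moxd1 (ENSMUSG00000020000), a monooxygenase-like gene, had the lowest log2 fold change of the named genes, −9.62 ± 2.09 (adjusted p = 0.0202). Its level was 155.8 and 116.7 CPM in MCS replicates 1 and 2 and 0.772 CPM in MCS replicate 3, against 0.0450 to 0.139 CPM on the MCD diet. Moxd1 did not pass without MCS replicate 2, MCD replicate 1, MCD replicate 2 or MCD replicate 3 (adjusted p = 0.0563 to 0.183). Moxd1 did not pass on the log2(TPM + 1) scale, by limma-voom or without a count filter (log2 fold change −9.63 to −3.97, adjusted p = 0.0612 to 0.610). Moxd1 moved by 0.62 and −0.59 on the log2 scale without MCS replicate 1 and MCS replicate 3. Cyp2a4 is a near copy of Cyp2a5, and the sum of both did not pass the test (0.48 ± 0.38, adjusted p = 0.380), so its rise is uncertain as a change of the pair. The sum of Gsta1, Gsta2 and Gm3776 rose by 4.77 ± 0.76 (adjusted p = 0.00726), and by 6.00 without MCS replicate 3.

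**Figure D1:**
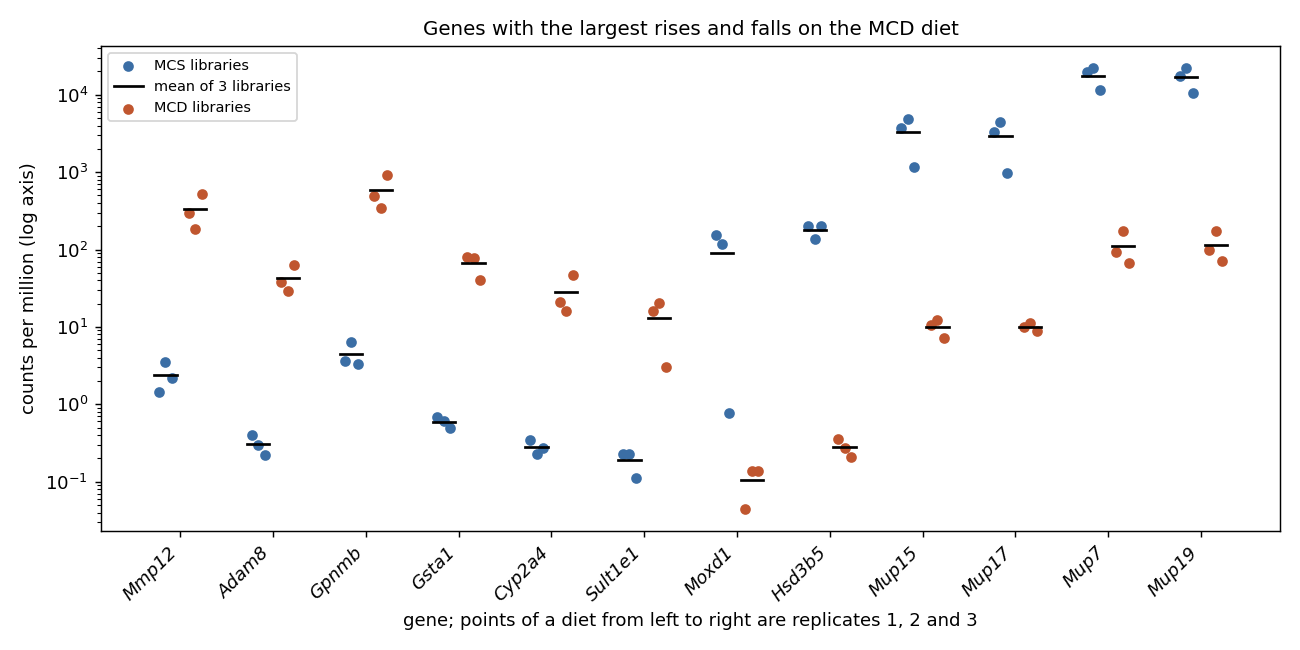
CPM (log axis) in each library for the 6 genes with the largest rises and the 6 with the largest falls among genes past the threshold with a mean of at least 5 CPM, no overlap and a symbol other than a predicted-gene name; blue points are MCS libraries, orange points MCD libraries and black lines the mean of 3 libraries. The diets do not overlap for any of the 12 genes, and MCS replicate 3 lies at 0.772 CPM for Moxd1, apart from 155.8 and 116.7 CPM in the other MCS libraries.

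In all, 3117 of 12599 tested genes changed at adjusted p under 0.05 (edgeR's quasi-likelihood test), 1861 upward and 1256 downward, and 1822 of them by a fold above 2 (1386 up, 436 down). The libraries of the diets did not overlap for 3095 of the 3117 genes (99.3%). Among all tested genes this share was 45.3%, and chance gives 10%. The share among called genes is no separate support, because the test itself favours genes without overlap. The direction split depends on scaling. With TMM 59.7% of calls rose and the median log2 fold change of all genes was 0.01. With library size alone 5443 genes were called, 93.6% of them upward (5095 up, 348 down), and the median was 0.57. The changes reported here are relative to the bulk of the genes. Leaving out MCS replicate 1, MCS replicate 2 or MCD replicate 1 lowered the count to 1379, 1347 or 1472 genes. Leaving out MCD replicate 2 raised the genes that fell to 2072. At adjusted p under 0.01, 1058 genes passed. Without both MCS replicates 1 and 2, a setting chosen after seeing the data that leaves a single control library, 74 genes passed, and 23 of 75 called genes chosen by the rule for naming genes passed.

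In the authors' deposited table, 4772 genes had a false discovery rate under 0.05, 4486 of them higher and 286 lower on the MCD diet, and 3635 also had a fold above 2 (3453 higher, 182 lower). Of those 4772 genes, 2094 were also called here, all 2094 in the same direction as in the authors' deposited table, and 229 were not among the genes tested here. Another 1023 genes were called here and not in the authors' deposited table. The authors' deposited table gives fold changes as ratios of mean TPM, whose median over the genes tested here was 0.69 on the log2 scale.

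Lists of genes fixed before the data were examined were compared with all other genes by camera with a preset correlation of 0.01, and 23 of 35 lists passed at adjusted p under 0.05 (10 up, 13 down). With an estimated correlation 0 of 35 lists passed, 3 had an unadjusted p under 0.05, and the lowest adjusted p was 0.372; by fry, which tests a list against no change and not against other genes, 14 passed. Each of the other 9 splits of the 6 libraries into 3 and 3, which mix the diets, also had lists called by camera with the preset correlation, between 9 and 23. A list that passed camera is therefore not by itself evidence of a difference between the diets. Counts of changed members are therefore given with each list. Without MCS replicates 1 and 2 the neutrophil, VLDL and female-biased lists did not pass (adjusted p = 0.137, 0.0605 and 0.0821). The sinusoidal endothelial, cholesterol, mitochondrially encoded and ribosomal protein lists, none of which passed with all libraries, passed there (adjusted p = 0.000349, 1.32e-06, 0.0424 and 0.00300). With a replicate block the stellate cell and cholesterol lists passed (adjusted p = 0.00774 and 0.0453).

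Replicates differed in markers of cell types other than hepatocytes. Among the MCD libraries, replicate 3 was highest for 17 of 18 recruited macrophage markers, 30 of 30 extracellular matrix genes, 12 of 12 stellate cell markers, 12 of 12 sinusoidal endothelial markers and 10 of 11 cholangiocyte markers. MCD replicate 2 was highest for 18 of 18 hepatocyte identity genes and 20 of 20 acute phase proteins. Among the MCS libraries, replicate 3 was highest for 12 of 12 sinusoidal endothelial and 10 of 12 stellate cell markers.

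Markers of lipid-associated and recruited macrophages rose: of 18 tested members 17 rose and 1, Fabp5, did not pass (0.25 ± 0.74, adjusted p = 0.832), with a median log2 fold change of 3.69. The same 17 rose when adjusted over the list alone. Besides Mmp12 and Gpnmb, Lgals3 and Cd63, a galectin and a lysosomal tetraspanin, rose by 4.47 ± 0.27 and 3.73 ± 0.26 (adjusted p = 8.67e-05 and 0.000156). The list passed camera (adjusted p = 8.78e-13; adjusted p = 0.372 with an estimated correlation). Resident Kupffer cell markers mostly did not pass: 3 of 12 fell, 0 rose and 9 did not pass (3 fell adjusted over the list alone). Clec4f, a Kupffer cell lectin, and Cd163, a haemoglobin scavenger receptor, fell by 1.20 and 2.65 on the log2 scale (adjusted p = 0.0148 and 0.0315). Their list did not pass (adjusted p = 0.270), and its median of 0.04 differs in sign from its mean of −0.49 and the downward direction of camera. With library size alone it passed downward (adjusted p = 0.0330), where its median was 0.61. Clec4f did not pass without MCS replicate 2 (adjusted p = 0.0537); Cd163 did not pass without MCS replicate 1, MCS replicate 2, MCD replicate 1 or MCD replicate 3 (adjusted p = 0.0515 to 0.124). Clec4f did not pass with library size alone or on either TPM scale (log2 fold change −0.65 to −0.58, adjusted p = 0.0929 to 0.115). Cd163 did not pass without a count filter (log2 fold change −2.65, adjusted p = 0.0677). Fabp5 had a log2 fold change of 1.03 and −0.37 without MCS replicate 1 and MCD replicate 3. Cd163 had a log2 fold change of −3.99 without MCD replicate 2. Kupffer cell calls numbered 4 up and 2 down with library size alone, 1 down without MCS replicate 1 or MCD replicate 1, and 0 down without MCS replicate 2.

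Inflammatory cytokines, chemokines and related adhesion molecules and receptors also rose. Of 19 tested members 14 rose and 5 did not pass (17 rose adjusted over the list alone), the median was 1.88, and the list passed camera (adjusted p = 1.94e-08; adjusted p = 0.372 with an estimated correlation). The adhesion molecule Icam1 and the endotoxin co-receptor Cd14 rose by 1.88 ± 0.14 and 2.94 ± 0.29 (adjusted p = 0.000202 and 0.000489). The monocyte chemokine Ccl2 rose by 4.85 ± 0.84 (adjusted p = 0.00540), and Ccl3, with 0 counts in the MCS libraries and 107 in the MCD libraries, was at least 23.8-fold higher against a floor of 3 counts over the group (95% counting interval from 19.0; 14.9 to 27.8 with 1 library left out, the lowest without MCS replicate 3). Il1b had a log2 fold change of −0.23 ± 0.42 (adjusted p = 0.713) and Tnf of 2.56 ± 1.12 (adjusted p = 0.125). Among 18 interferon-stimulated genes 4 rose, 1 fell and 13 did not pass (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.267, median 0.28, or 0.87 with library size alone). The guanylate-binding protein Gbp2 and the oligoadenylate synthetase-like Oasl2 rose by 1.47 ± 0.30 and 1.22 ± 0.28 (adjusted p = 0.0107 and 0.0167). The transcription factor Irf7 fell by 0.64 (adjusted p = 0.0222). Oasl2 did not pass without MCS replicate 1 or MCS replicate 2 (adjusted p = 0.0676 to 0.0701); Irf7 did not pass without MCS replicate 1, MCS replicate 2 or MCD replicate 1 (adjusted p = 0.0816 to 0.102). Irf7 did not pass with library size alone, with library sizes without abundant and Mup genes or on either TPM scale (log2 fold change −0.29 to 0.06, adjusted p = 0.194 to 0.777). Tnf passed without MCS replicate 2 (adjusted p = 0.0284). Tnf passed by limma-voom and on either TPM scale (log2 fold change 1.05 to 3.69, adjusted p = 0.0185 to 0.0485). Ccl2 had a log2 fold change of 4.26 without MCS replicate 1, and had 0 counts in the MCS libraries left without MCS replicate 3. Tnf had a log2 fold change of 1.90 and 1.89 without MCS replicate 1 and MCS replicate 3, and had 0 counts in the MCS libraries left without MCS replicate 2. Cytokine and chemokine calls numbered 16 up and 0 down with library size alone. Interferon-stimulated calls numbered 8 up and 0 down with library size alone, 1 up without MCS replicate 1 or MCS replicate 2, 2 up without MCD replicate 1, and 3 down without MCD replicate 3.

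Lymphocyte and neutrophil markers were low and mostly did not pass. Of 12 tested T and NK cell markers 3 rose and 9 did not pass (3 rose adjusted over the list alone; median 0.61, or 1.22 with library size alone, camera adjusted p = 0.150): the chemokine Ccl5 and the T cell receptor subunit Cd3e, among these 3, rose by 2.80 ± 0.39 and 2.21 ± 0.66 (adjusted p = 0.00215 and 0.0387). Of 5 tested B cell and plasma cell markers 1 rose, the receptor Cd22 (1.54 ± 0.40, adjusted p = 0.0232), and 4 did not pass (1 rose adjusted over the list alone; median 0.35, or 0.92 with library size alone, camera adjusted p = 0.203). Among 5 tested neutrophil markers 2 rose and 3 did not pass (2 rose adjusted over the list alone). Ly6g, Retnlg, Cxcr2, Ltf, Ngp and Camp, also on the neutrophil list, were not tested, so its result rests on the tested members only. With a median of 1.39 the list passed camera (adjusted p = 0.0493; adjusted p = 0.555 with an estimated correlation and adjusted p = 0.105 by fry). The granulocyte colony-stimulating factor receptor Csf3r rose from 1.97 ± 0.753 to 7.94 ± 4.69 CPM (adjusted p = 0.0167), and the neutrophil collagenase Mmp8 had 1 count in the MCS and 60 in the MCD libraries, a ratio of 40.0 with a 95% counting interval of 6.92 to 1607. Without MCS replicate 1, which held the 1 count, Mmp8 was at least 8.59-fold higher against the floor, and the ratio was 25.1 to 46.0 without another library, the lowest without MCS replicate 3. Cd3e did not pass without MCS replicate 1, MCS replicate 2, MCS replicate 3, MCD replicate 1 or MCD replicate 3 (adjusted p = 0.0712 to 0.138). Cd22 did not pass without MCS replicate 1, MCS replicate 2 or MCD replicate 3 (adjusted p = 0.0509 to 0.0888). Csf3r did not pass without MCS replicate 1 or MCS replicate 2 (adjusted p = 0.0600 to 0.0633). Cd3e did not pass by limma-voom or without a count filter (log2 fold change 2.13 to 2.21, adjusted p = 0.0559 to 0.0687). Cd22 did not pass by limma-voom (log2 fold change 1.51, adjusted p = 0.0562). Csf3r did not pass by limma-voom (log2 fold change 1.93, adjusted p = 0.0612). The neutrophil markers list did not pass without MCS replicate 1 or MCD replicate 3 (adjusted p = 0.0512 to 0.115). With library size alone it had adjusted p = 0.480. The T and NK cell markers list passed without MCS replicate 3 or MCD replicate 2 (adjusted p = 0.0184 to 0.0343). Csf3r had a log2 fold change of 1.40 without MCD replicate 3. T and NK cell calls numbered 5 up and 0 down with library size alone, and 1 up without MCS replicate 1, MCS replicate 2, MCS replicate 3, MCD replicate 1 or MCD replicate 3. Without MCD replicate 3 there was also 1 call down. T and NK cell medians were 1.23, 1.67, 1.83, 1.97 and −0.01 without MCS replicate 1, MCS replicate 2, MCS replicate 3, MCD replicate 2 and MCD replicate 3. B cell and plasma cell medians moved by 0.94 without MCS replicate 3. Neutrophil calls numbered 1 up without MCS replicate 1 or MCS replicate 2, and 4 up without MCD replicate 2. Neutrophil medians were 2.02, 2.01 and 0.51 without MCS replicate 3, MCD replicate 2 and MCD replicate 3.

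Extracellular matrix and fibrosis genes rose. Of 30 tested members 22 rose and 8 did not pass (28 rose adjusted over the list alone), with a median of 2.14. The collagenase Mmp13 rose by 5.63 ± 0.70 (adjusted p = 0.00136) and the basement membrane collagen Col4a1 from 42.5 ± 1.67 to 170.4 ± 70.4 CPM (adjusted p = 0.00240). The fibrillar collagen Col1a1 and the metalloprotease inhibitor Timp1 rose by 2.97 ± 0.63 and 4.95 ± 1.02 (adjusted p = 0.0181 and 0.0128). Smooth muscle actin Acta2 had a log2 fold change of 1.82 ± 0.57 (adjusted p = 0.0516). Camera gave adjusted p = 1.22e-07 for the list (adjusted p = 0.555 with an estimated correlation and adjusted p = 0.125 by fry). Quiescent stellate cell markers did not pass as a list (camera adjusted p = 0.0591, median 1.04, or 1.64 with library size alone): 2 of 12 rose, among them the transcription factor Hand2 (1.20 ± 0.34, adjusted p = 0.0314), and 10 did not pass (2 rose adjusted over the list alone). Hand2 did not pass without MCS replicate 1, MCS replicate 2, MCD replicate 1 or MCD replicate 3 (adjusted p = 0.0702 to 0.113). Hand2 did not pass by limma-voom (log2 fold change 1.15, adjusted p = 0.0794). Col1a1 did not pass without MCS replicate 2, MCD replicate 1 or MCD replicate 3 (adjusted p = 0.0556 to 0.0940). Timp1 did not pass without MCS replicate 2 (adjusted p = 0.0618). Acta2 passed without MCD replicate 2 (adjusted p = 0.00500). Col1a1 did not pass without a count filter (log2 fold change 2.96, adjusted p = 0.0534). Timp1 did not pass by limma-voom (log2 fold change 5.29, adjusted p = 0.0656). Acta2 passed by DESeq2, with the GC trend removed, with the length trend removed, with library size alone, with library sizes without abundant and Mup genes, with non-robust dispersions and on either TPM scale (log2 fold change 1.69 to 2.44, adjusted p = 0.00480 to 0.0497). The quiescent stellate cell markers list passed without MCS replicate 3 or MCD replicate 2 (adjusted p = 0.00444 to 0.00532). Mmp13 had a log2 fold change of 5.04 without MCS replicate 1, and had 1 count in the MCS libraries left without MCS replicate 3. Col1a1 had a log2 fold change of 2.39 without MCD replicate 3. Timp1 had a log2 fold change of 4.32 and 4.23 without MCS replicate 3 and MCD replicate 3, and had 1 count in the MCS libraries left without MCS replicate 1. Extracellular matrix calls numbered 28 up and 0 down with library size alone, 9 up without MCS replicate 1, 4 up without MCS replicate 2, and 10 up without MCD replicate 1. Stellate cell calls numbered 7 up and 0 down with library size alone, 1 up without MCS replicate 1, MCS replicate 2, MCD replicate 1 or MCD replicate 3, and 6 up without MCD replicate 2.

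Cholangiocyte markers rose: of 11 tested members 8 rose and 3 did not pass (10 rose adjusted over the list alone), with a median of 1.83 (camera adjusted p = 0.000287; adjusted p = 0.372 with an estimated correlation). The tight junction protein Cldn4 and the epithelial adhesion molecule Epcam rose by 4.63 ± 0.68 and 2.54 ± 0.38 (adjusted p = 0.00273 and 0.00302). Sinusoidal endothelial cell markers did not pass: 0 of 12 were called by edgeR, by DESeq2 or by limma-voom, 0 had an unadjusted p under 0.05, and camera gave adjusted p = 0.326 (median −0.36, 0.25 with library size alone; 0 called adjusted over the list alone). All 12 were highest in replicate 3 of each diet, and the median was 0.39 without MCS replicate 3 and −1.62 without MCD replicate 3. The scavenger receptor Stab2 was at 21.8, 33.6 and 90.4 CPM in the MCS and 21.9, 24.9 and 59.6 CPM in the MCD libraries. With library size alone the list passed downward (adjusted p = 0.00328). The sinusoidal endothelial cell markers list passed without MCD replicate 3 (adjusted p = 0.00590). Hepatocyte identity genes were lower as a list (camera adjusted p = 0.000197; adjusted p = 0.555 with an estimated correlation and adjusted p = 0.103 by fry), with a median of −0.72, or −0.20 with library size alone. Of its 18 members 5 fell and 13 did not pass (10 fell adjusted over the list alone). The tyrosine-degrading enzymes Tat and Hpd fell by 1.39 and 1.54 on the log2 scale (adjusted p = 0.0108 and 0.0167). Albumin, Alb, had a log2 fold change of −0.04 ± 0.36 (adjusted p = 0.951). Tat did not pass without MCS replicate 2 or MCD replicate 1 (adjusted p = 0.0505 to 0.0579); Hpd did not pass without MCS replicate 2 or MCD replicate 1 (adjusted p = 0.0530 to 0.0811). Alb passed on either TPM scale (log2 fold change 0.62, adjusted p = 0.0449 to 0.0498). Cholangiocyte calls numbered 11 up and 0 down with library size alone, and 5 up without MCS replicate 2. Hepatocyte identity calls numbered 0 up and 3 down with library size alone, 2 down without MCS replicate 1, 0 down without MCS replicate 2 or MCD replicate 1, 3 down without MCS replicate 3 or MCD replicate 3, and 11 down without MCD replicate 2.

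**Figure D2:**
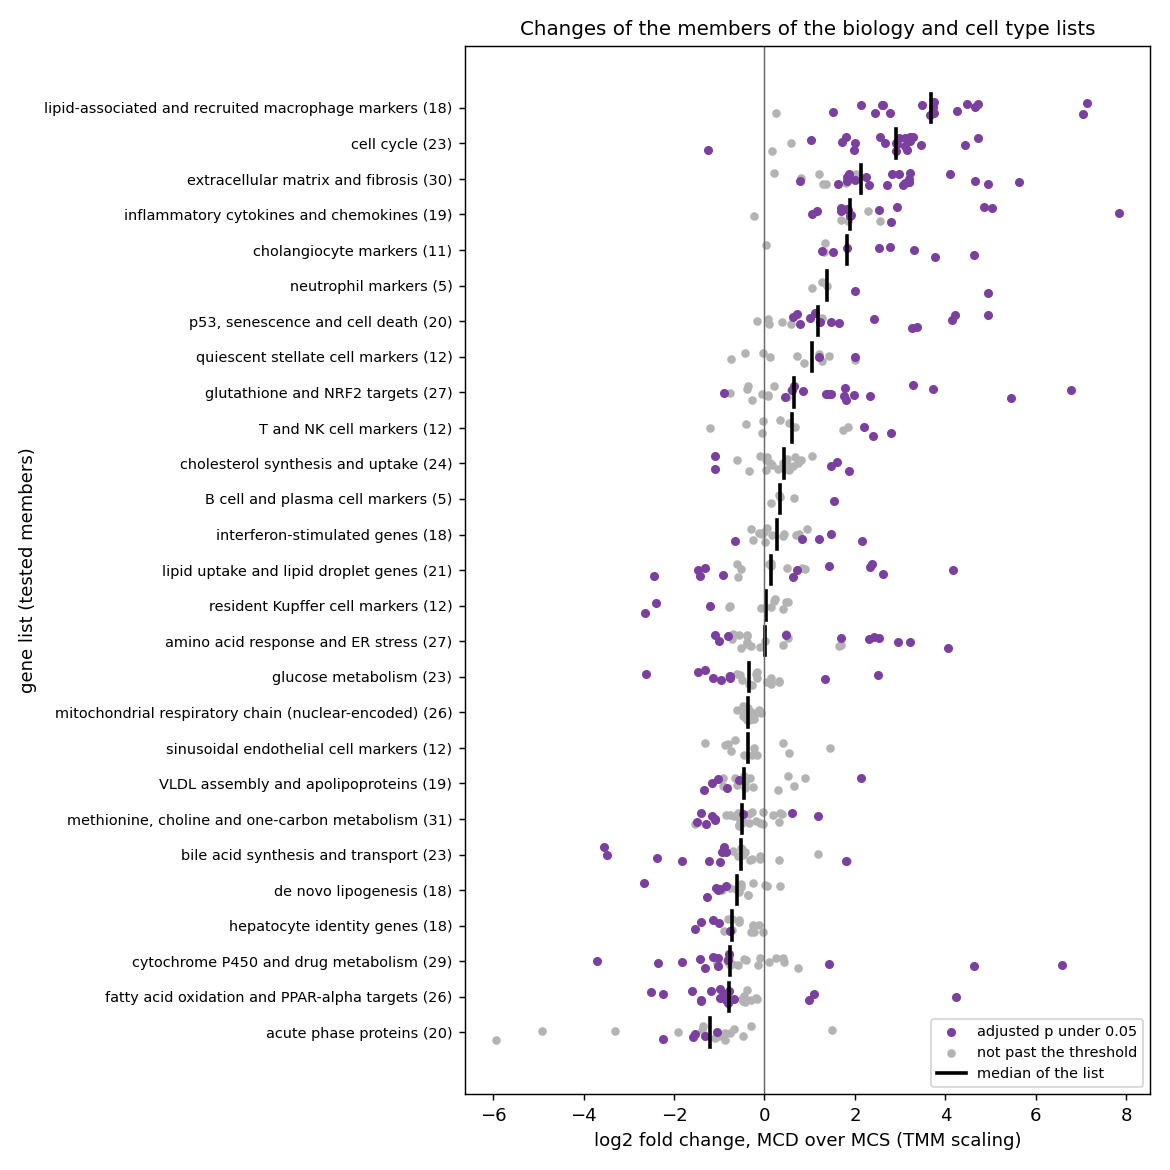
Log2 fold change of MCD over MCS (horizontal axis) for each tested member of the 27 biology and cell type lists (vertical axis, with the number of tested members); purple points passed at adjusted p under 0.05, grey points did not, and black bars are list medians. The medians run from −1.21 for acute phase proteins to 3.69 for macrophage markers on the TMM scale; with library size alone the medians of the bile acid, methionine, VLDL, glucose, respiratory chain and sinusoidal endothelial lists are above 0.

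Cell cycle genes rose: of 23 tested members 20 rose, 1 fell and 2 did not pass (20 rose and 1 fell adjusted over the list alone), with a median of 2.91. Cyclin D1, Ccnd1, rose from 27.8 ± 2.14 to 209 ± 52.4 CPM (2.91 ± 0.22, adjusted p = 0.000193) and the mitotic kinase Cdk1 by 3.15 ± 0.41 (adjusted p = 0.00158). Thymidine kinase, Tk1, fell by 1.24 (adjusted p = 0.00471). Camera gave the list adjusted p = 2.21e-08 (adjusted p = 0.372 with an estimated correlation). Genes of p53 response, senescence and cell death rose with them: 14 of 20 tested members rose and 6 did not pass (14 rose adjusted over the list alone). With a median of 1.18 the list passed camera (adjusted p = 7.87e-07; adjusted p = 0.372 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose from 0.926 ± 0.209 to 29.1 ± 4.09 CPM (4.95 ± 0.22, adjusted p = 2.72e-05), and Tnfrsf12a, the receptor of TWEAK, by 2.42 ± 0.22 (adjusted p = 0.000424). Cell cycle calls numbered 21 up and 1 down with library size alone. Senescence and cell death calls numbered 15 up and 0 down with library size alone.

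Fatty acid oxidation genes and PPAR-alpha targets fell: of 26 tested members 15 fell, 3 rose and 8 did not pass (16 fell and 3 rose adjusted over the list alone), with a median of −0.79, or −0.25 with library size alone. The acyl-CoA thioesterase Acot1 and the omega-hydroxylase Cyp4a10 fell by 2.50 and 2.25 (adjusted p = 0.000397 and 0.00172). The summed Cyp4a10 family fell from 2776 ± 595 to 605 ± 124 CPM (adjusted p = 0.00153). Pdk4, an inhibitor of pyruvate oxidation, rose by 4.24 ± 0.46 (adjusted p = 0.00161), as did the hormone gene Fgf21 (1.09 ± 0.21, adjusted p = 0.00884) and the thioesterase Acot2 (0.98 ± 0.22, adjusted p = 0.0141). The list passed camera (adjusted p = 3.16e-06; adjusted p = 0.372 with an estimated correlation). De novo lipogenesis genes had a median of −0.60, or −0.07 with library size alone, with 6 of 18 members lower and 12 not past the threshold (6 fell adjusted over the list alone; camera adjusted p = 0.000316; adjusted p = 0.387 with an estimated correlation and adjusted p = 0.0543 by fry). Malic enzyme Me1, the transcription factor Mlxipl and the desaturase Scd1 fell by 1.26, 1.02 and 2.67 (adjusted p = 0.00145, 0.0128 and 0.0211). The synthase Fasn had a log2 fold change of 0.34 ± 0.21 (adjusted p = 0.274). Mlxipl did not pass without MCS replicate 1 (adjusted p = 0.0539). Scd1 did not pass without MCS replicate 1, MCD replicate 1, MCD replicate 2 or MCD replicate 3 (adjusted p = 0.0515 to 0.127). Mlxipl did not pass with library size alone or on either TPM scale (log2 fold change −0.50 to −0.37, adjusted p = 0.0546 to 0.122). Scd1 did not pass on either TPM scale (log2 fold change −1.66 to −1.65, adjusted p = 0.0850 to 0.107). Fasn passed with library size alone, with library sizes without abundant and Mup genes and on either TPM scale (log2 fold change 0.69 to 0.96, adjusted p = 0.00842 to 0.0413). Fatty acid oxidation calls numbered 4 up and 8 down with library size alone, 8 down without MCS replicate 1, 7 down without MCS replicate 2, and 6 down without MCD replicate 1. Lipogenesis calls numbered 2 up and 3 down with library size alone, 1 down without MCS replicate 1, 3 down without MCS replicate 2, and 2 down without MCD replicate 1.

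Lipid uptake and lipid droplet genes went both ways: 7 of 21 rose, 5 fell and 9 did not pass (7 rose and 7 fell adjusted over the list alone; median 0.15, or 0.69 with library size alone, camera adjusted p = 0.446). The droplet coat protein Plin4 and the fatty acid translocase Cd36 rose by 2.33 ± 0.21 and 2.63 ± 0.29 (adjusted p = 0.000424 and 0.000855). The lipolysis inhibitor G0s2 fell by 2.45 (adjusted p = 0.00145). Very-low-density lipoprotein (VLDL) assembly genes and apolipoproteins had a median of −0.44, which was 0.06 with library size alone; 5 of 19 fell, 1 rose and 13 did not pass (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0455; adjusted p = 0.587 with an estimated correlation and adjusted p = 0.140 by fry). The lipid transfer protein Mttp, needed to load triglyceride onto apolipoprotein B, and the carboxylesterase Ces1d fell by 1.02 and 1.34 (adjusted p = 0.0114 and 0.0132). The RNA-editing enzyme Apobec1 rose by 2.14 ± 0.23 (adjusted p = 0.000821). Mttp did not pass without MCS replicate 1, MCS replicate 2 or MCD replicate 1 (adjusted p = 0.0506 to 0.0593); Ces1d did not pass without MCD replicate 1 (adjusted p = 0.0666). Mttp did not pass on either TPM scale (log2 fold change −0.34, adjusted p = 0.0888 to 0.0904). The VLDL assembly and apolipoproteins list did not pass without MCS replicate 1, MCS replicate 3, MCD replicate 1 or MCD replicate 3 (adjusted p = 0.0550 to 0.115). Lipid uptake and droplet calls numbered 12 up and 4 down with library size alone, 4 up without MCS replicate 2, and 3 down without MCD replicate 1. VLDL calls numbered 5 up and 3 down with library size alone, 2 up without MCS replicate 3, 3 up without MCD replicate 2, 1 down without MCS replicate 1 or MCS replicate 2, 0 down without MCD replicate 1, 10 down without MCD replicate 2, and 3 down without MCD replicate 3.

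Cholesterol synthesis and uptake genes did not pass as a list (camera adjusted p = 0.150, median 0.43, or 0.97 with library size alone); 3 of 24 rose, 2 fell and 19 did not pass (3 rose and 2 fell adjusted over the list alone). The synthase Hmgcs1 and the decarboxylase Mvd of the mevalonate pathway rose by 1.86 ± 0.33 and 1.47 ± 0.32 (adjusted p = 0.00594 and 0.0138). The sterol reductase Tm7sf2 fell by 1.09 (adjusted p = 0.00693). Mvd did not pass without MCD replicate 1 (adjusted p = 0.0585). The cholesterol synthesis and uptake list passed without MCS replicate 1, MCS replicate 2 or MCD replicate 3 (adjusted p = 0.0140 to 0.0373). Bile acid synthesis and transport genes were lower relative to other genes (camera adjusted p = 0.000318; adjusted p = 0.372 with an estimated correlation), with a median of −0.51, or 0.01 with library size alone. Of 23 members 9 fell, 1 rose and 13 did not pass (11 fell and 2 rose adjusted over the list alone). The oxysterol hydroxylase Cyp7b1 and the organic anion transporter Slco1a1, both also on the male-biased list, fell by 3.48 and 3.55 (adjusted p = 0.000889 and 0.00136). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of −0.43 ± 0.37 (adjusted p = 0.424), and the efflux pump Abcc4 rose by 1.81 ± 0.50 (adjusted p = 0.0307). Abcc4 did not pass without MCS replicate 1, MCS replicate 2, MCD replicate 1 or MCD replicate 3 (adjusted p = 0.0511 to 0.113). Abcc4 had a log2 fold change of 2.50 without MCS replicate 3. Cholesterol calls numbered 13 up and 2 down with library size alone, and 1 up without MCD replicate 1. Bile acid calls numbered 4 up and 6 down with library size alone, and 2 up without MCS replicate 3 or MCD replicate 2.

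In methionine, choline and one-carbon metabolism, the pathways that use the nutrients missing from the MCD diet, 7 of 31 genes fell, 2 rose and 22 did not pass (10 fell and 2 rose adjusted over the list alone). The list had a median of −0.49, or 0.01 with library size alone, and camera gave adjusted p = 0.00414 (adjusted p = 0.564 with an estimated correlation and adjusted p = 0.125 by fry). The transsulfuration enzyme Cbs and the serine hydroxymethyltransferase Shmt1 fell by 1.40 and 1.10 (adjusted p = 0.0111 and 0.0165). Choline kinase Chka rose by 1.18 ± 0.22 (adjusted p = 0.00706). Shmt1 did not pass without MCS replicate 1, MCS replicate 2, MCS replicate 3 or MCD replicate 1 (adjusted p = 0.0502 to 0.0531). Shmt1 did not pass on either TPM scale (log2 fold change −0.46, adjusted p = 0.0804 to 0.0863). The amino acid response and ER stress list did not pass (camera adjusted p = 0.522, median 0.01, or 0.56 with library size alone): 8 of 27 rose, 3 fell and 16 did not pass (10 rose and 6 fell adjusted over the list alone). The stress regulator Nupr1 and the transcription factor Atf3 rose by 3.21 ± 0.42 and 4.07 ± 0.51 (adjusted p = 0.00161 and 0.00252). The serine synthesis enzymes Psat1 and Phgdh rose by 2.42 ± 0.38 and 2.96 ± 0.69 (adjusted p = 0.00346 and 0.0161). The ER chaperone Hyou1 fell by 1.09 (adjusted p = 0.0189). Hyou1 did not pass without MCS replicate 1, MCS replicate 2 or MCD replicate 3 (adjusted p = 0.0586 to 0.0762). Phgdh did not pass without MCS replicate 1, MCS replicate 2 or MCS replicate 3 (adjusted p = 0.0527 to 0.0708). Hyou1 did not pass with library size alone, with library sizes without abundant and Mup genes or on either TPM scale (log2 fold change −0.74 to −0.37, adjusted p = 0.0598 to 0.230). Phgdh had a log2 fold change of 2.36 without MCD replicate 3. Methionine and choline calls numbered 8 up and 2 down with library size alone, 1 up without MCS replicate 1, MCS replicate 2, MCS replicate 3, MCD replicate 1 or MCD replicate 2, 1 down without MCS replicate 1, MCS replicate 2, MCS replicate 3 or MCD replicate 1, 14 down without MCD replicate 2, and 4 down without MCD replicate 3. Amino acid response calls numbered 12 up and 0 down with library size alone, 5 up without MCS replicate 3, 0 down without MCS replicate 1, MCS replicate 2 or MCD replicate 3, and 5 down without MCS replicate 3.

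Glutathione and NRF2 target genes rose: of 27 members 16 rose, 1 fell and 10 did not pass (17 rose and 2 fell adjusted over the list alone), with a median of 0.64, or 1.20 with library size alone (camera adjusted p = 9.50e-06; adjusted p = 0.372 with an estimated correlation). Besides Gsta1, the glutathione transferase Gstm3 rose by 5.44 ± 0.33 (adjusted p = 8.67e-05), the summed Gstm family by 1.77 ± 0.37 (adjusted p = 0.0107) and the quinone reductase Nqo1 by 2.33 ± 0.21 (adjusted p = 0.000396). Superoxide dismutase Sod1 fell by 0.89 (adjusted p = 0.0242). Sod1 did not pass without MCS replicate 1, MCS replicate 2, MCS replicate 3 or MCD replicate 1 (adjusted p = 0.0674 to 0.107). Sod1 did not pass with the length trend removed, with library size alone or on either TPM scale (log2 fold change −0.69 to −0.24, adjusted p = 0.0558 to 0.257). The fixed list of cytochrome P450 and other drug-metabolizing genes was lower (camera adjusted p = 0.000762; adjusted p = 0.593 with an estimated correlation and adjusted p = 0.113 by fry; median −0.77, or −0.24 with library size alone). Of 29 tested members 10 fell, 3 rose and 16 did not pass (15 fell and 4 rose adjusted over the list alone). Cyp2c29 and the glucuronosyltransferase Ugt2b1 fell by 3.70 and 1.82 (adjusted p = 0.000193 and 0.000849). Cyp2a4 was among the members that rose. The annotated pathway of drug metabolism by cytochrome P450 went the other way: 14 of its 54 genes rose with a fold above 2, where 6.76 would be drawn by chance (hypergeometric test, adjusted p = 0.0450), 6 of them glutathione transferases, and 3 fell (adjusted p = 0.926). Its call was lost without MCD replicate 2 or MCD replicate 3 (adjusted p = 0.0609 to 0.277). The summed Cyp2c family fell by 1.10 (adjusted p = 0.0256) and the summed Cyp2b family rose by 4.66 ± 1.16 (adjusted p = 0.0304). The summed Gstm family did not pass without MCS replicate 1 or MCS replicate 2 (adjusted p = 0.0595 to 0.0607). The summed Cyp2c family did not pass without MCS replicate 1, MCS replicate 2, MCS replicate 3 or MCD replicate 1 (adjusted p = 0.0723 to 0.101). The summed Cyp2b family did not pass without MCS replicate 1, MCS replicate 2, MCD replicate 1, MCD replicate 2 or MCD replicate 3 (adjusted p = 0.0702 to 0.135). The summed Cyp2b family had a log2 fold change of 7.87 and 3.62 without MCS replicate 3 and MCD replicate 2. Glutathione and NRF2 calls numbered 21 up and 0 down with library size alone, 10 up without MCS replicate 1, MCS replicate 2 or MCD replicate 1, and 3 down without MCD replicate 2. P450 list calls numbered 8 up and 6 down with library size alone, 1 up without MCS replicate 1, MCS replicate 2 or MCD replicate 1, 6 down without MCS replicate 1, 5 down without MCS replicate 2, MCS replicate 3 or MCD replicate 1, and 17 down without MCD replicate 2.

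Glucose metabolism genes had a median of −0.33, or 0.17 with library size alone, and 7 of 23 fell, 2 rose and 14 did not pass (9 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.0162; adjusted p = 0.372 with an estimated correlation). The gluconeogenic enzyme Fbp1 and the transcription factor Foxo1 fell by 1.47 and 0.76 (adjusted p = 0.00609 and 0.00606). Foxo1 did not pass with library size alone or on either TPM scale (log2 fold change −0.22 to −0.09, adjusted p = 0.144 to 0.650). The pyruvate kinase Pkm rose by 2.52 ± 0.29 (adjusted p = 0.00120). Nuclear-encoded respiratory chain genes passed camera (adjusted p = 0.00153; adjusted p = 0.679 with an estimated correlation and adjusted p = 0.310 by fry) with a median of −0.36, or 0.15 with library size alone. Yet 0 of its 26 members were called by edgeR, by DESeq2 or by limma-voom, 0 were called adjusted over the list alone, and 1 had an unadjusted p under 0.05. The ATP synthase subunit Atp5b had 1414 ± 234 CPM on the MCS and 1201 ± 306 CPM on the MCD diet. The mitochondrial respiratory chain (nuclear-encoded) list did not pass without MCS replicate 3 (adjusted p = 0.0513). It did not pass with library size alone either (adjusted p = 0.109). MCS replicate 3 and MCD replicate 2 were the highest of their diets for all 26. Glucose calls numbered 5 up and 5 down with library size alone, 1 up without MCS replicate 1, MCS replicate 2, MCD replicate 1 or MCD replicate 3, 3 down without MCS replicate 1 or MCD replicate 1, and 2 down without MCS replicate 2. Respiratory chain calls numbered 1 up and 0 down with library size alone, and 7 down without MCD replicate 2.

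Male-biased liver genes fell and female-biased liver genes rose. Of 15 tested male-biased genes 13 fell and 2, Mup20 and Selenbp2, did not pass (13 fell adjusted over the list alone). With a median of −3.19 the list passed camera (adjusted p = 5.58e-14; adjusted p = 0.372 with an estimated correlation). Hsd3b5 had the smallest p of the list, and the elongase Elovl3 and the summed Cyp4a12a and Cyp4a12b hydroxylases fell by 2.91 and 3.37 (adjusted p = 0.000397 and 0.000433). Of 9 tested female-biased genes 7 rose, 1 fell and 1 did not pass (7 rose and 1 fell adjusted over the list alone). With a median of 3.31 the list passed camera (adjusted p = 0.0124; adjusted p = 0.372 with an estimated correlation). Its median is the value of Prom1, also on the cholangiocyte list, which rose; without Prom1 the median was 3.10, 6 of 8 rose and camera gave adjusted p = 0.0211 (adjusted p = 0.412 with an estimated correlation). Cyp2b13, with 0 counts in the MCS and 197 in the MCD libraries, was at least 43.8-fold higher against a floor of 3 counts over the group (95% counting interval from 35.3). With 1 library left out the bound was 18.2 to 60.1, the lowest without MCD replicate 2, where 57 of the 197 counts were left. The steroid hydroxylase Cyp17a1 fell by 2.11 (adjusted p = 0.0164). The female-biased list did not pass camera with library size alone (adjusted p = 0.321). Cyp17a1 did not pass without MCS replicate 1 or MCD replicate 1 (adjusted p = 0.0507 to 0.0715). Cyp17a1 had a log2 fold change of −2.74 without MCD replicate 2. Female-biased calls numbered 4 up without MCD replicate 3. Female-biased medians were 2.66, 2.35, 2.51 and 2.48 without MCS replicate 1, MCS replicate 2, MCS replicate 3 and MCD replicate 1.

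Acute phase proteins, secreted by hepatocytes in inflammation, were lower on the MCD diet as a list (camera adjusted p = 0.00142; adjusted p = 0.607 with an estimated correlation and adjusted p = 0.381 by fry), with a median of −1.21, or −0.68 with library size alone; 5 of 20 fell, 0 rose and 15 did not pass (9 fell adjusted over the list alone). The inhibitor heavy chain Itih4 and fibrinogen alpha, Fga, fell by 2.24 and 1.31 (adjusted p = 0.0228 and 0.0318). The MCS libraries differed among themselves: serum amyloid Saa1 was at 4855 and 3907 CPM in MCS replicates 1 and 2, 30.5 CPM in MCS replicate 3 and 64.4, 169.9 and 56.4 CPM in the MCD libraries (−4.92 ± 1.57, adjusted p = 0.0638). Lipocalin Lcn2 was at 1361, 1135 and 15.2 CPM against 381, 738 and 371 CPM (−0.75 ± 1.20, adjusted p = 0.681). Haptoglobin, Hp, was at 16571, 15799 and 3366 CPM against 4474, 6454 and 2901 CPM (−1.37 ± 0.58, adjusted p = 0.114). With MCS replicates 1 and 2 both left out, a setting chosen after seeing the data, the list lay in the opposite direction and did not pass (adjusted p = 0.0985). Itih4 did not pass without MCS replicate 1, MCS replicate 2, MCD replicate 1 or MCD replicate 3 (adjusted p = 0.0791 to 0.0937); Fga did not pass without MCS replicate 1, MCS replicate 2, MCD replicate 1 or MCD replicate 3 (adjusted p = 0.0542 to 0.126). Saa1 passed without MCS replicate 3 (adjusted p = 0.00221). Lcn2 passed without MCS replicate 3 (adjusted p = 0.0382). Hp passed without MCS replicate 3 (adjusted p = 0.0230). Itih4 did not pass on the log2(TPM + 0.1) scale (log2 fold change −1.41, adjusted p = 0.0573). Fga did not pass on either TPM scale (log2 fold change −0.63, adjusted p = 0.0637 to 0.0703). Saa1 passed by DESeq2, with library size alone, with library sizes without abundant and Mup genes and with non-robust dispersions (log2 fold change −4.93 to −4.41, adjusted p = 0.00546 to 0.0464). Saa1 had a log2 fold change of −5.50 and −5.63 without MCS replicate 3 and MCD replicate 2. Acute phase calls numbered 1 up and 4 down with library size alone, 0 down without MCS replicate 1, MCS replicate 2, MCD replicate 1 or MCD replicate 3, 13 down without MCS replicate 3, and 8 down without MCD replicate 2.

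**Figure D3:**
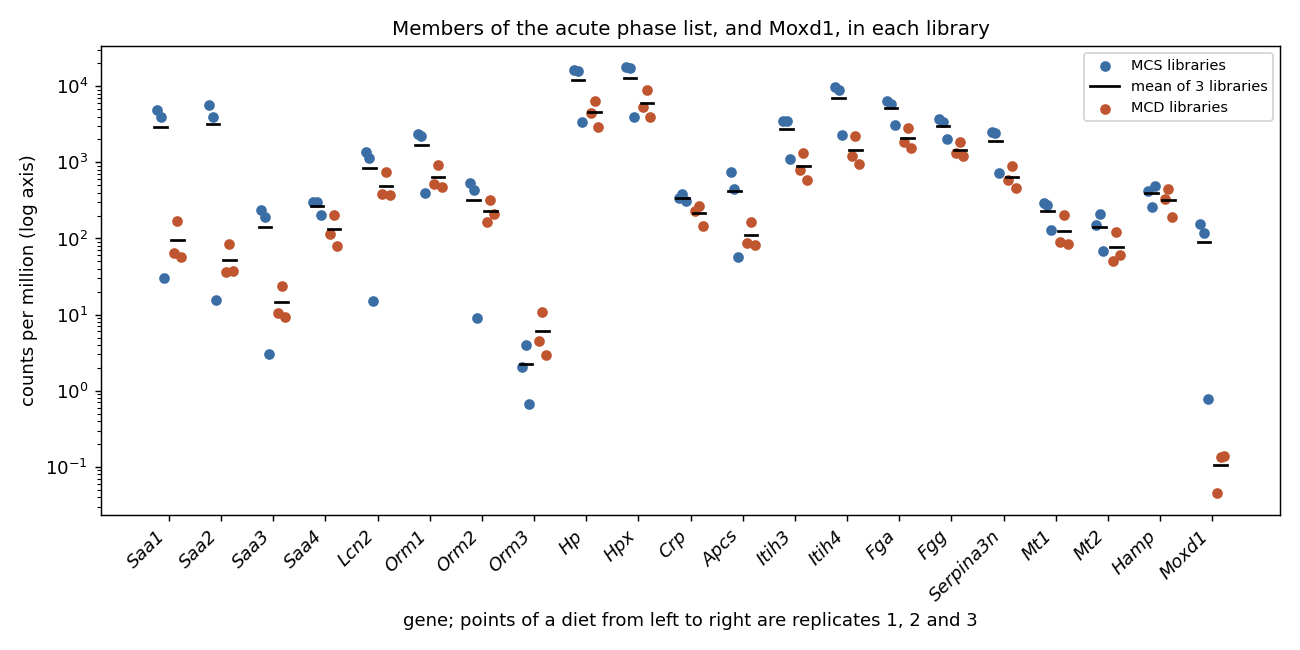
CPM (log axis) in each library for the 20 members of the acute phase list and Moxd1; blue points are MCS libraries, orange points MCD libraries, each in the order of replicates 1 to 3, and black lines are means of 3 libraries. Saa1 lies at 4855 and 3907 CPM in MCS replicates 1 and 2 and at 30.5 CPM in MCS replicate 3, below the MCD libraries (56.4 to 169.9 CPM).

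Pathways named in the deposited annotation were tested for an excess of genes with a fold above 2 (692 up and 222 down among 5527 annotated tested genes) by a one-sided hypergeometric test. Each of 319 pathways was tested in both directions. Of these 638 tests 78 passed at adjusted p under 0.05, 54 for genes that rose and 24 for genes that fell, in 77 pathways, of which 1 passed both ways. Cytokine-cytokine receptor interaction held 54 genes that rose among 144, where 18.0 would be drawn by chance (adjusted p = 4.96e-12). Chemokine signaling held 43 of 146 (adjusted p = 1.69e-06), hematopoietic cell lineage 27 of 63 (adjusted p = 1.66e-07) and phagosome 36 of 127 (adjusted p = 4.14e-05). Cell cycle held 32 of 115 (adjusted p = 0.000205) and extracellular matrix-receptor interaction 21 of 61 (adjusted p = 0.000218). Genes that fell were in excess in complement and coagulation cascades, 21 of 78 where 3.13 would be drawn by chance (adjusted p = 4.31e-10), and in steroid hormone biosynthesis, 18 of 63 (adjusted p = 4.13e-09). They were also in excess in arachidonic acid metabolism, 15 of 49 (adjusted p = 5.33e-08), PPAR signaling, 16 of 69 (adjusted p = 6.15e-07), and retinol metabolism, 15 of 72 (adjusted p = 5.44e-06). Without MCS replicate 1, MCD replicate 1 or MCD replicate 3, 41, 42 or 42 tests passed, and at adjusted p under 0.01 19 passed. Extracellular matrix-receptor interaction was lost without any 1 library other than MCD replicate 2 (adjusted p = 0.114 to 0.901). Hematopoietic cell lineage was lost without MCS replicate 1 or MCS replicate 2 (adjusted p = 0.0562 to 0.0986), and complement and coagulation cascades without MCS replicate 1 or MCD replicate 1 (adjusted p = 0.0641 to 0.149).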

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

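Tests without MCS replicates 1 and 2, with the GC trend removed and with library sizes without abundant and Mup genes were chosen after seeing the data. Between 2685 and 3762 genes were called with DESeq2 size factors, upper-quartile factors, library sizes without the 50 most abundant genes, either count filter, DESeq2, limma-voom, non-robust dispersions, the length trend removed and the GC trend removed (main result 3117); DESeq2 shared 3055 of the calls, and the fits without the length and GC trends 2869 and 2622. Of 75 called named genes, 23 were called in every setting. Library size alone gave 5443 genes (5095 up, 348 down), 3002 by a fold above 2; library sizes without abundant and Mup genes and no factor gave 3345 up and 525 down; log2(TPM + 1) gave 5636 (5382 up, 254 down) and log2(TPM + 0.1) 5921 (5658 up, 263 down), 3175 by a fold above 2. These settings lack the TMM factor. On the TPM scales Irf7 had a log2 fold change of 0.06 (0.0597 and 0.0604) and mt-Co1 of 0.605 on both (adjusted p = 0.0463 and 0.0418), against −0.06 with TMM. An adjusted p under 0.01 left 1058 genes (754 up, 304 down), 887 by a fold above 2, and 19 pathway tests. Leaving out 1 library gave 1347 to 4435 genes, 946 to 2363 up, 400 to 2072 down, 1099 to 2591 by a fold above 2 and 41 to 95 pathway tests; the lowest counts came without MCS replicate 1 (1379), MCS replicate 2 (1347) or MCD replicate 1 (1472), with fewer samples. Without MCS replicates 1 and 2, 74 genes passed (46 up, 28 down), 74 by a fold above 2, the lone control being assumed to vary like the MCD libraries, and the acute phase list turned upward (adjusted p = 0.0985); the cause was not tested. With an estimated correlation 0 of 35 lists passed and by fry 14. The replicate block gave 3283 genes, 2857 shared with the 3117, 84 pathway tests and 25 lists; same-number correlations of deviations were 0.06, 0.15 and 0.25, and not every sample correlated best with its own number, so the numbers were not taken to pair samples.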

Other observations

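Lists kept as checks were fixed beforehand. Tests of explanations below were chosen after the result was seen, other than the splits of the libraries. Several lists kept as checks passed camera with TMM scaling. Of 20 immediate early genes, which respond within minutes to stimuli, 9 rose, 0 fell and 11 did not pass (11 rose adjusted over the list alone; median 1.55; camera adjusted p = 1.68e-05; adjusted p = 0.446 with an estimated correlation). The transcription factor Myc rose by 2.67 ± 0.25 on the log2 scale (edgeR adjusted p = 0.000427), and Atf3 and Btg2 also stand on other lists. Of 17 circadian clock genes 5 fell and 12 did not pass (6 fell adjusted over the list alone; median −0.35, or 0.19 with library size alone; camera adjusted p = 0.0169; adjusted p = 0.372 with an estimated correlation), and the clock repressor Nr1d1 fell by 1.43 (edgeR adjusted p = 0.00632). Of 6 erythrocyte genes 1 fell, the haem synthesis enzyme Alas2, by 1.73 (edgeR adjusted p = 0.000485), and 5 did not pass (5 fell adjusted over the list alone; median −1.46, or −0.83 with library size alone; camera adjusted p = 0.00153; adjusted p = 0.372 with an estimated correlation). Immediate early calls numbered 15 up and 0 down with library size alone. Clock calls numbered 4 up and 2 down with library size alone, 2 down without MCS replicate 1 or MCS replicate 2, and 3 down without MCS replicate 3 or MCD replicate 1. Erythrocyte calls numbered 5 down without MCD replicate 3.

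Of 5 tested markers of pancreas, adipose tissue and gut, 1 rose, 3 fell and 1 did not pass (1 rose and 3 fell adjusted over the list alone; median −0.56, or −0.01 with library size alone; camera adjusted p = 0.260). The microvillus protein Vil1, also found in bile duct epithelium, had 1 count in the MCS and 72 in the MCD libraries, a ratio of 48.0 with a 95% counting interval of 8.35 to 1924. Without MCS replicate 3, which held the 1 count, Vil1 was at least 10.1-fold higher against a floor of 3 counts over the group, and the ratio was 30.9 to 55.5 without another library, the lowest without MCS replicate 1. The adipose factor Cfd fell by 4.65 on the log2 scale (edgeR adjusted p = 0.0235). Cfd did not pass without MCS replicate 1, MCS replicate 2 or MCD replicate 1 (adjusted p = 0.0547 to 0.0832). Cfd did not pass by DESeq2 (log2 fold change −4.66, adjusted p = 0.0583). Mitochondrially encoded genes had a median of −0.21, or 0.31 with library size alone (camera adjusted p = 0.0768); 0 of 13 were called by edgeR or limma-voom, also adjusted over the list alone, 2 were called by DESeq2, and 1 had an unadjusted p under 0.05. The oxidase subunit mt-Co1 had 20042 ± 4344 CPM on the MCS and 19162 ± 3606 CPM on the MCD diet. Cytosolic ribosomal protein genes had a median of −0.12, or 0.42 with library size alone (camera adjusted p = 0.168); 0 of 24 were called by edgeR, DESeq2 or limma-voom, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. Rps2 had a log2 fold change of −0.41 ± 0.24 (edgeR adjusted p = 0.233). The mitochondrially encoded genes list passed without MCD replicate 2 (adjusted p = 0.00453). The cytosolic ribosomal protein genes list passed without MCS replicate 2 (adjusted p = 0.0498). Cfd had a log2 fold change of −3.87 and −3.99 without MCS replicate 2 and MCD replicate 3, and had 0 counts in the MCD libraries left without MCD replicate 2. Other-tissue calls numbered 1 up and 1 down with library size alone, and 0 down without MCS replicate 1, MCS replicate 2 or MCD replicate 1. Mitochondrially encoded calls numbered 1 up and 0 down with library size alone, and 3 down without MCD replicate 2. Ribosomal protein calls numbered 9 up and 0 down with library size alone.

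The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split, 1 of the 10, gave 3117 genes changed, 1822 with a fold above 2 and 78 pathway tests, and the highest of the other splits gave 0 for each by edgeR (at most 876 genes at an unadjusted p under 0.05). Each of the other splits mixes the diets within its groups, so the diet difference adds to their spread and few calls are possible. With 0 genes called, the fold and pathway counts could only be 0. No conclusion is drawn from these zeros. For gene lists the real split gave 23 and the others 9 to 23, so 2 splits reached 23. Besides the real split, this was the split that joins MCD replicate 2 to MCS replicates 1 and 2.

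Male-biased genes fell and female-biased genes rose together (medians −3.19 and 3.31, the latter 3.10 without Prom1, which is also on the cholangiocyte list). Female animals among the MCD samples are argued against by the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, whose lowest sum on the MCD diet was 1.09 times the lowest on the MCS diet. Reads moved between near-identical Mup copies are argued against, for the Mup genes, by the summed family (log2 fold change −3.08). A lower hepatocyte share may add to the fall of the male-biased genes but is argued against as its whole cause. The medians of the male-biased and hepatocyte lists differed by −2.48, and by −2.91 to −2.28 with libraries left out. A permutation test over genes gave p = 0.00015. It takes genes as independent, though near-identical copies are on the male-biased list, and does not measure the spread between libraries. A change in hormonal control of these genes on the MCD diet may underlie the pattern and was not tested.

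The share of calls that rose was 59.7% with TMM and 93.6% with library size alone. A few abundant genes taking most of the counts may add to this shift but are argued against as its whole cause: with library sizes without the 50 most abundant and the Mup genes the median of all genes was 0.37, against 0.57 with full library sizes, and between 0.27 and 0.46 with each library left out. A lower hepatocyte share with the other cell types in unchanged proportions would raise their markers alike. The medians of the macrophage and sinusoidal endothelial lists instead differed by 4.06 on the library size scale (permutation test over genes, p = 1e-05, the smallest these permutations can give). They differed by 3.10 to 4.84 with 1 library or both replicates 3 left out. The sinusoidal markers varied together between replicates, and this p takes genes as independent, so it does not measure the spread between libraries. A rise of only some cell types would also lower the hepatocyte share, and the difference between these lists cannot argue against that. A change in cell composition or in RNA per cell on the MCD diet stays open and was not tested.

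Most acute phase transcripts were high in MCS replicates 1 and 2 and low in MCS replicate 3. Among the MCS libraries, replicate 1 was highest for 15 of 20, replicate 2 for 4 and replicate 3 for 1, Hamp (423.5, 259.5 and 490.0 CPM). Crp differed little (335.8, 381.5 and 311.2 CPM). A wrong label by which MCS replicate 3 is an MCD sample is argued against: over 1596 genes called without it with a fold above 2, its median position was 0.17 (quartiles −0.02 and 0.39) on a scale from the other MCS libraries (0) to the MCD libraries (1). A difference in depth or scaling is argued against, since without a scaling factor the median gene differed by 0.11 between MCS replicate 3 and the mean of the others, whereas the acute phase list differed by −1.90, and such a cause would move all genes alike. An infection or injury or a batch may account for the high values, and the labels give nothing to test these, so no biological explanation was tested.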
